A study of Mus musculus with 2 samples.

How the data were processed

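Total RNA from the neural tube of B6NCrl mouse embryos at 15.5 days was measured in 2 libraries, biological replicates 1 and 2 per the labels, from pools of 78 and 62 embryos of both sexes. Per the labels' protocols, RNA longer than 200 nucleotides was extracted with a mirVana kit, 10 ng entered each library, exogenous spike-in RNAs were added, and the manual of a low-input SMARTer kit is linked. The libraries form 1 group, so nothing could be compared between conditions, and every SD and p-value measures only these pools or the spread over genes.

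The authors deposited 1 gene table and 1 transcript table per library on build mm10 with GENCODE release M4, derived from transcriptome alignments, per the notes deposited with each sample. The aligner, the quantifier, their versions and the use of strand are not given in the sources used here. Per the file headers, the tables hold an expected count per gene or transcript, in which reads that fit several transcripts are shared out by a model. They also hold TPM as deposited by the authors, scaled to 1 common total over all entries, spike-ins included. FPKM is given relative to effective length and library size, per the file headers. The percent of a gene's TPM in each transcript is given in the deposited transcript tables. Posterior mean values and the bounds of their intervals, a score per the file headers, were deposited too, and the bounds were not used. The length of a gene exceeded its effective length by 99 in 99.99% of genes.

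Each gene table has 69691 entries: 43346 genes, 96 spike-ins, 1 phage control and 26248 entries named by a number alone. Spike-ins took 2.12% of counts in replicate 1 and 2.28% in replicate 2, and 5.00% and 5.42% of TPM. The number-only entries and the phage control were left out of all gene analyses. Gene symbols, types and coordinates came from GENCODE release M21 on GRCm38, the assembly that mm10 names, matched by identifier without version: 42462 matched and 884 did not. Gene expected counts summed to 34678043 in replicate 1 and 41355355 in replicate 2. At that depth, 3 counts correspond to 0.0878 TPM for Tuba1a and 0.148 TPM for Cd3g in replicate 1, and intervals or floors from counts cover counting error only.

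Lists, pairs, rules and tests were fixed before the data were examined. A gene was called detected at 1 TPM or more in both libraries. The 39 fixed lists hold 469 distinct genes, all found in the tables. For 7 contrasts, the difference between mean log2(TPM + 1) of the lists was computed per library and tested by two-sided permutation of genes between lists, with 100000 resamples where both lists had 10 or more genes and exact enumeration otherwise, adjusted by Benjamini-Hochberg over the 7. These tests treat genes as exchangeable, and genes are not independent replicates. For 15 gene pairs and 16 genes with isoforms, ratios and shares were taken per library with their mean and SD. Genes apart between the libraries had an absolute log2((TPM + 1) ratio) of at least 1, a mean of at least 5 TPM and at least 50 summed expected counts. List shifts are the median log2 ratio of members at or above 1 TPM in either library, set against 10000 random lists matched on size and on 20 bins of mean expression. Lists with fewer than 4 such members were left out. The 95% bootstrap ranges given with some medians came from 10000 resamples of the genes of a list. They measure the spread over genes and not that between pools.

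Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave TMM scaling and the dispersion of the group, and for DESeq2 1.42.0 size factors (0.926 and 1.08), both in R 4.3.3. Everything else ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data. Among 20485 simulated genes of 2 libraries, 200 were changed 4-fold, of which 184 (92%) were recovered and 0 unchanged genes were called. Of random lists with no shift, 5% fell outside the central 95%, and of lists shifted by 0.5 on the log2 scale, 100% fell outside. Of contrasts with no difference, 6% passed 0.05, and of those with a difference of 3, 95% did. The simulated genes varied independently and less than in the real pools, whose common biological coefficient of variation was 0.362. The simulation therefore checked the steps only and gives no rate of false calls for these pools.

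Named genes followed a fixed rule: the 20 highest genes, up to 4 of the highest and 3 of the lowest members of each list with members under 1 TPM in both libraries, the genes of the pairs and isoforms, and the 10 largest differences between the libraries each way. Other members are named where a list's description needs them, and were chosen after their values were seen. The 14 gene lists for thymus, gut and other tissues were written after the largest differences between the libraries had been seen. The wider thymocyte and thymic epithelium lists were written from genes outside those differences, before their own values were seen. The values of some genes that this rule names are not reported here. Alternatives covered the unit (FPKM, posterior means, CPM), thresholds of 0.5 and 5 TPM, a pseudocount of 0.1, filters on low values, TMM, DESeq2 and spike-in scaling, and each replicate left out.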

Results

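RNA from the neural tube of mouse embryos at 15.5 days was sequenced as total RNA in 2 libraries. The neural tube is the embryonic structure that forms the brain and spinal cord. Each library came from its own pool of B6NCrl embryos of both sexes, 78 embryos for replicate 1 and 62 for replicate 2, so the libraries were biological replicates of 1 group and no comparison between conditions existed. The questions open to these data were which regions, cell types and stages of maturation the tissue held and how far the pools differed. The expected counts summed to 35430338 in replicate 1 and 42321669 in replicate 2. In total, 15505 of 43346 annotated genes reached 1 TPM (transcript abundance corrected for length and library size) in both libraries, with 16726 in replicate 1 and 16001 in replicate 2. Levels below are mean TPM ± SD over the libraries (n = 2), unless both values are given.

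Transcripts of the neuronal cytoskeleton, haemoglobin and mitochondria were the most abundant products of protein-coding genes. Tuba1a (ENSMUSG00000072235.5; chromosome 15, 98949837 to 98953703), the main tubulin of young neurons, stood at 10958 ± 1809 TPM. It lay above Actb at 4865 ± 235 TPM, with a Tuba1a to Actb ratio of 2.26 ± 0.48 (n = 2). Among the 20 highest genes were also Hba-a2 at 6248 ± 649 TPM, Stmn1 at 3678 ± 497 TPM, Tmsb4x at 3944 ± 355 TPM, Tmsb10 at 3624 ± 559 TPM, Ftl1 at 4201 ± 256 TPM, Ppia at 3859 ± 109 TPM and Ubb at 3465 ± 175 TPM. The long noncoding RNA Malat1 reached 6981 ± 796 TPM. The signal recognition particle RNAs Rn7s1 and Rn7s2 led the table at 14089.8 ± 324 and 14089.8 ± 323 TPM. These are near-identical copies on chromosome 12, so the split of reads between them was uncertain. The mitochondrial transcripts mt-Atp6, mt-Atp8, mt-Rnr2 and mt-Cytb stood at 8639 ± 311, 6587 ± 52.6, 3748 ± 159.7 and 3686 ± 177 TPM. Gm28437 (9364 ± 229 TPM) and Gm28661 (3382 ± 13.6 TPM), pseudogenes on chromosome 1, and Gm10123 (3304 ± 39.7 TPM), a processed pseudogene on chromosome 9, may share reads with their parent genes. Gm22133, a microRNA gene at 3969 ± 48.5 TPM, lies within Ftl1, and its reads cannot be separated from those of Ftl1 here.

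Hox genes, which set position along the trunk, were expressed across most of their clusters, while regulators of forebrain and midbrain were close to absent. Of 39 Hox genes, 33 reached 1 TPM in both libraries, and 0 of 18 forebrain and midbrain regulators did. The Hox list exceeded the forebrain and midbrain list by 3.43 ± 0.33 in mean log2(TPM + 1) (SD, n = 2), in 2 of 2 libraries. In a two-sided permutation test over genes, p was 1e-05, the smallest that 100000 resamples can give, and the Benjamini-Hochberg adjusted p over 7 contrasts was 3.5e-05. Otx2 stood at 0.055 ± 0.0778 TPM, and Otx1, Six3, Nkx2-1 and En2 at 0 in both libraries. With a pseudocount of 0.1 TPM the difference was 5.52. At 0.5 TPM, or from CPM, which divides counts by library size only, 2 regulators were detected. Without replicate 2, 2 members reached 1 TPM, among them Dlx1 (1.12 and 0.1 TPM in replicates 1 and 2).

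The highest Hox transcripts came from the middle of the clusters. Hoxa7 (ENSMUSG00000038236.7; chromosome 6, 52214491 to 52221854) stood at 101 ± 17.4 TPM, Hoxb6 at 100.1 ± 15.1, Hoxb7 at 88.6 ± 7.46 and Hoxc8 at 67.5 ± 29.8. Paralogue groups 5 to 9 held 65.1% of the summed Hox TPM in replicate 1 and 73.0% in replicate 2. Groups 1 to 4 held 10.3% and 12.8%, and groups 10 to 13 held 24.6% and 14.2%. Of the groups active at lumbar levels, the highest were Hoxd10 at 59.7 ± 12.8 TPM, Hoxc10 at 50.2 ± 11.5 TPM and Hoxa10 at 48.7 ± 12.1 TPM. Hoxa13, Hoxd13, Hoxd12 and Hoxb1 stayed under 1 TPM in both libraries, at 0.13 ± 0.099, 0.14 ± 0.0424, 0.33 ± 0.0283 and 0.43 ± 0.156. By cluster, the sums were 289 ± 47.0 TPM for Hoxa, 395 ± 76.3 for Hoxb, 230.3 ± 43.6 for Hoxc and 116 ± 8.09 for Hoxd. On build mm10 the Hoxa genes span chromosome 6 from 52155590 to 52260880 and the Hoxb genes chromosome 11 from 96194316 to 96368256. The Hoxc genes span chromosome 15 from 102921103 to 103036852 and the Hoxd genes chromosome 2 from 74668310 to 74765142. Neighbouring and antisense transcripts overlap in these clusters, for example Hoxd3 and Hoxd4, and the use of strand in the counting is not given in the sources used here.

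**Figure D1:**
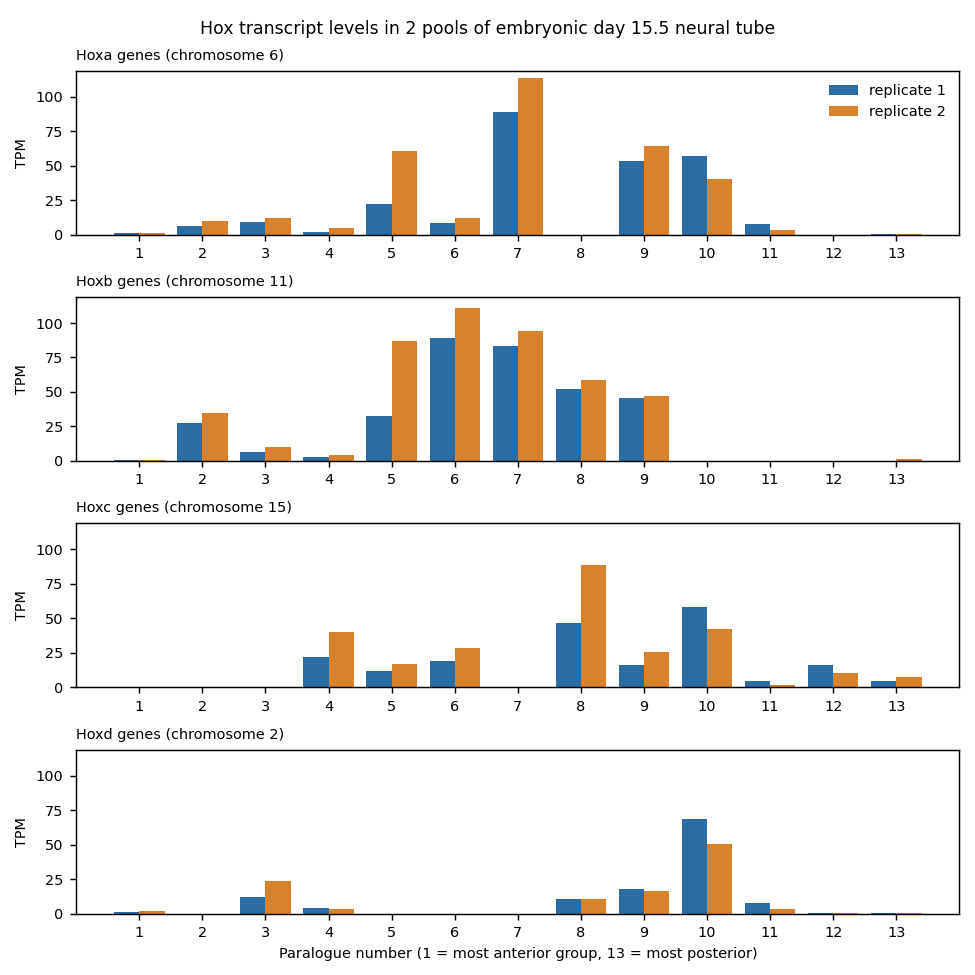
TPM (vertical axis) of each Hox gene by paralogue number (horizontal axis) in the 4 clusters, with blue bars for replicate 1 and orange bars for replicate 2. The largest bars lie at paralogues 5 to 10, where Hoxb5 stood at 32.4 TPM in replicate 1 and 86.7 in replicate 2.

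The median of the listed neuronal genes far exceeded that of the listed progenitor genes. All 15 pan-neuronal genes were detected, with a median of 263 ± 24.8 TPM, led by Tubb3 at 1167 ± 152 TPM, Gap43 at 1049 ± 161 TPM, Stmn2 at 974 ± 146 TPM and Nefl at 819 ± 47.2 TPM. The lowest members were Elavl3 at 51.95 ± 14.02 TPM, Rbfox3 at 73.4 ± 10.8 TPM and L1cam at 74.6 ± 5.44 TPM. Of 15 progenitor and radial glia genes, 13 were detected, with a median of 16.5 ± 3.61 TPM. Fabp7, a lipid-binding protein of radial glia, stood at 1625 ± 294 TPM, Vim at 386 ± 29.05 and Slc1a3 at 141 ± 2.31, against 9.16 ± 1.15 for Sox2 and 8.49 ± 1.23 for Pax6. Sox1 and Sox3 stayed under 1 TPM (0.53 ± 0.297 and 0.565 ± 0.375). The pan-neuronal list exceeded the progenitor list by 3.40 ± 0.15 in mean log2(TPM + 1) (n = 2, permutation p = 0.00031, adjusted p = 0.0007), in 2 of 2 libraries. The lists differ in the kinds of gene they hold, such as Tubb3 and Nefl against Sox2 and Pax6. The test therefore does not measure the share of neurons among the cells.

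The listed genes of young neurons were on average more abundant than the listed genes of mature neurons. The early neuronal list exceeded the late neuronal list by 4.04 ± 0.08 in mean log2(TPM + 1) (n = 2, permutation p = 0.0004, adjusted p = 0.0007), in 2 of 2 libraries. The early list also holds very abundant cytoskeletal genes such as Tuba1a, so the test does not separate stage from kind of gene. All 16 early genes were detected, among them Crmp1 at 596 ± 71.4 TPM, Dpysl3 at 879 ± 87.4 TPM and Sox11 at 145 ± 23.8 TPM, and the lowest was Nhlh1 at 1.99 ± 0.191 TPM. Of 14 late genes, 13 were detected, with Vamp1 at 45.6 ± 2.02 TPM, Slc12a5 at 34.6 ± 5.76 TPM, Nefh at 18.9 ± 1.07 TPM and Syt2 at 17.8 ± 1.73 TPM, while Pvalb stood at 3.87 ± 0.318 TPM and Kcna2 at 0.44 ± 0. Within fixed pairs, Dcx exceeded Rbfox3 by 2.63 ± 0.12-fold and the juvenile NMDA receptor subunit Grin2b exceeded Grin2a by 3.06 ± 0.24-fold in TPM (n = 2). From CPM, which is not divided by transcript length, their log2 ratios were 2.60 in place of 1.39 and 3.27 in place of 1.61. Slc12a5, the chloride exporter of maturing neurons, already exceeded the importer Slc12a2 by 9.92 ± 1.83-fold. Ptbp2, the neuronal splicing repressor, and Ptbp1, its counterpart in other cells, differed between the libraries, with a log2 ratio of 0.16 in replicate 1 and 1.48 in replicate 2. Transcripts of thymus and epithelium, such as Prss16 (136 and 0.07 TPM) and Krt8 (266 and 1.97 TPM), were also far higher in replicate 1 than in replicate 2.

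Genes that start neuronal differentiation were low. Of 13 neurogenic factors, 7 were detected, with Hes6 at 117 ± 33.6 TPM, Dll3 at 15.9 ± 0.672 TPM, Olig3 at 13.4 ± 1.36 TPM and Neurod1 at 11.4 ± 3.4 TPM at the top. Neurog1, Neurog3, Neurod4, Atoh1 and Ptf1a stayed under 1 TPM in both libraries (0.075 ± 0.106, 0.385 ± 0.247, 0.275 ± 0.0354, 0.46 ± 0.0283 and 0.095 ± 0.134 TPM). Progenitor genes exceeded the neurogenic factors by 2.47 ± 0.01 in mean log2(TPM + 1) (n = 2, permutation p = 0.0114, adjusted p = 0.016). The progenitor list also holds genes of other kinds, such as Vim and Fabp7, so this difference does not measure shares of cells. With members under 1 TPM left out, that difference was 1.91 and its adjusted permutation p was 0.076. The glial factor Nfia exceeded Neurog2 by 16.8 ± 5.88-fold in TPM, and their log2 ratio was 5.94 from CPM in place of 4.02.

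Genes of dorsal and ventral interneurons, progenitor domains and motor neurons were detected. All 17 dorsal interneuron genes were detected, and 10 at a threshold of 5 TPM, led by Prrxl1 at 108 ± 7.93 TPM, Pou4f1 at 54.1 ± 8.38 TPM, Isl1 at 40.6 ± 1.3 TPM and Pax8 at 32.8 ± 2.23 TPM, with the lowest at 1.35 ± 0.212 (Barhl2), 1.43 ± 0.177 (Phox2a) and 1.54 ± 0.0636 TPM (Dmrt3). Prrxl1, Pou4f1 and Isl1 are also genes of dorsal root ganglion neurons. Of 14 ventral interneuron genes, 8 were detected, and 5 at 5 TPM, led by Foxp2 at 13.02 ± 1.03 TPM, Gata3 at 12.9 ± 0.191 TPM and Shox2 at 8.81 ± 2.74 TPM. Evx2, En1, Sim1 and Foxn4 were under 1 TPM in both libraries (0.265 ± 0.106, 0.91 ± 0.0707, 0.265 ± 0.00707 and 0.02 ± 0.0141). Of 19 progenitor domain genes, 13 were detected, but 2 at 5 TPM, led by Msx1 at 9.53 ± 4.4 TPM and Olig2 at 7.8 ± 0.813 TPM, whereas Pax7, Nkx2-9, Gdf7, Gsx2, Lmx1a and Msx2 were under 1 TPM (0.13 ± 0.0141, 0.11 ± 0.0141, 0.06 ± 0.0849, 0.105 ± 0.0919, 0.455 ± 0.148 and 0.7 ± 0.0424). Of 13 motor neuron genes, 12 were detected, among them Prph at 157 ± 12.3 TPM, Foxp1 at 46.8 ± 7.59 TPM and Aldh1a2 at 45.5 ± 6.75 TPM, the retinoic acid enzyme that meninges also express. Mnx1, a determinant of motor neurons, stood at 0.91 ± 0.198 TPM and Lhx4 at 3.44 ± 0.841.

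The glutamate transporter Slc17a6 and the GABA enzyme Gad1 were the highest transmitter genes. Slc17a6, the vesicular glutamate transporter of spinal neurons, stood at 82.4 ± 6.59 TPM and exceeded Slc32a1, the inhibitory vesicular transporter, by 9.66 ± 0.14-fold (n = 2). It exceeded Chat, the acetylcholine enzyme, by 23.5 ± 0.36-fold, although Slc18a3, the acetylcholine transporter encoded within the Chat locus, stood at 32.5 ± 3.57 TPM. Gad1 (73.6 ± 7.67 TPM) exceeded Gad2 by 2.89 ± 0.18-fold and the glycine transporter Slc6a5 by 5.43 ± 0.31-fold. Of 17 genes of transmitter synthesis and transport, 12 were detected. Slc17a7, Slc17a8, Dbh and Slc6a3 were under 1 TPM in both libraries (0.315 ± 0.12, 0.495 ± 0.0778, 0.275 ± 0.0495 and 0.1 ± 0.0283). Of 17 neuropeptide genes, 15 were detected, led by Npy at 273 ± 28.8 TPM, Sst at 255 ± 22.8 TPM, Tac1 at 169.9 ± 35.2 TPM and Penk at 126 ± 9.16 TPM, and the lowest were Trh at 1.07 ± 0.269 TPM, Vip at 1.6 ± 1.17 TPM and Nmu at 2.17 ± 0.0919 TPM. Ratios between different genes rest on the division by transcript length. From CPM, the log2 ratio of Slc6a5 to Gad1 was -1.29 in place of -2.44, that of Slc17a6 to Slc32a1 was 3.92 in place of 3.27 and that of Chat to Slc17a6 was -5.19 in place of -4.56.

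Genes of astrocytes and oligodendrocytes were detected at both early and later stages. Fabp7 and Slc1a3 belong to the early glial and the progenitor list alike. All 9 early glial genes were detected (median 44.4 ± 0.24 TPM), among them Nfix at 53.3 ± 5.82 TPM, Tnc at 49.8 ± 7.43 TPM and Nfia at 30.4 ± 1.39 TPM. All 10 mature astrocyte genes were detected too (median 14.4 ± 0.50 TPM), from Aldoc at 294 ± 30.6 TPM, Glul at 181 ± 10.1 TPM and Gja1 at 61.2 ± 2.82 TPM down to Gfap at 2.73 ± 1.03 TPM and Agt at 1.53 ± 0.0707 TPM. The early list exceeded the mature list by 1.69 ± 0.04 in mean log2(TPM + 1) (n = 2), which did not pass the exact two-sided permutation test (p = 0.0991, adjusted p = 0.12). That call was not kept under every setting: the adjusted permutation p was 0.024 on TMM-normalized CPM and 0.022 with medians over genes. Slc1a3 exceeded Gfap by 55.7 ± 21.8-fold, and their log2 ratio was 6.36 from CPM in place of 5.74. All 9 oligodendrocyte precursor genes were detected, with Olig1 at 67.3 ± 5.3 TPM, Ptprz1 at 22.8 ± 0.714 TPM, Pdgfra at 13.4 ± 1.8 TPM and Sox10 at 10.1 ± 0.898 TPM highest. Of 10 myelin genes, 7 were detected, and 4 at 5 TPM, including Cnp at 56.01 ± 7.43 TPM, Mbp at 29.6 ± 1.27 TPM and Cldn11 at 24.6 ± 0.24 TPM, while Mobp (0.225 ± 0.148) and Opalin (0.025 ± 0.0354) were under 1 TPM. The precursor list stood above the myelin list by 0.97 ± 0.06 in mean log2(TPM + 1), a difference that did not pass the exact permutation test (p = 0.222, adjusted p = 0.22) and that was 0.35 with members under 1 TPM left out, 1.58 with a pseudocount of 0.1 TPM and 1.61 on TMM-normalized CPM. Mbp exceeded Pdgfra by 2.23 ± 0.20-fold in TPM, an excess that was absent from CPM, where the log2 ratio of Pdgfra to Mbp was -0.0047 in place of -1.15. All 8 ependymal and cilia genes were detected, but 3 at 5 TPM, with Rfx3 at 16.1 ± 0.799 TPM, Spag6l at 12.3 ± 1.41 TPM and Foxj1 at 9.62 ± 0.424 TPM highest and Pifo at 2.73 ± 0.233 TPM lowest.

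Transcripts of blood, vessels, microglia, peripheral ganglia, mesenchyme, muscle and cartilage were also detected. Red cell genes took 1.41% of all TPM. Adult globins exceeded embryonic ones, with Hbb-bs over Hbb-y at 23.1 ± 10.8-fold and Hba-a1 over Hba-x at 71.3 ± 27.7-fold (log2 ratio 5.49 from CPM in place of 6.10), although globin copies share reads. Endothelium (9 of 10 genes), pericytes (7 of 7) and microglia (10 of 10) were detected, with Cldn5 at 95.3 ± 5.84 TPM, Kdr at 17.4 ± 1.56 TPM, Pdgfrb at 13.5 ± 4.43 TPM, C1qb at 51.05 ± 0.382 TPM and Csf1r at 13.5 ± 0.163 TPM. Slco1a4, an adult blood-brain barrier transporter, stood at 0.06 ± 0.0283 TPM. Acta2 of smooth muscle and mural cells differed between the libraries (175 and 17.9 TPM in replicates 1 and 2). Dorsal root ganglion genes were detected in 14 of 15 cases, among them P2rx3 at 16.9 ± 1.07 TPM and Avil at 17.1 ± 1.85 TPM, with Runx3 at 0.535 ± 0.53 TPM. Schwann and neural crest genes were detected in 6 of 8 cases, with Sox10 at 10.1 ± 0.898 TPM and Gfra3 at 10.3 ± 0.368 TPM and with Cdh19 at 0.79 ± 0.127 TPM. All 10 meningeal and mesenchymal genes were detected, led by Col3a1 at 359.7 ± 102 TPM, Col1a1 at 284 ± 33.7 TPM and Col1a2 at 206 ± 13.2 TPM. Skeletal muscle genes (10 of 10) included Acta1 at 109 ± 46.7 TPM and Mylpf at 43.2 ± 14.4 TPM, and cartilage genes (8 of 10, and 3 at 5 TPM) included Col2a1 at 39.7 ± 16.98 TPM and Cnmd at 15.5 ± 3.44 TPM, with Ucma at 0.245 ± 0.346 TPM. Of 6 choroid plexus genes, 1 was detected in both libraries, Folr1 (7.16 and 1.4 TPM), against 3 at 0.5 TPM and 0 at 5 TPM, and 3 reached 1 TPM in replicate 1 taken alone (Folr1, Ttr and Clic6). Ttr stood at 3.98 and 0.84 TPM, while Kl, Kcne2 and Otx2 were under 1 TPM in both (0.835 ± 0.0354, 0.185 ± 0.0919 and 0.055 ± 0.0778).

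**Figure D2:**
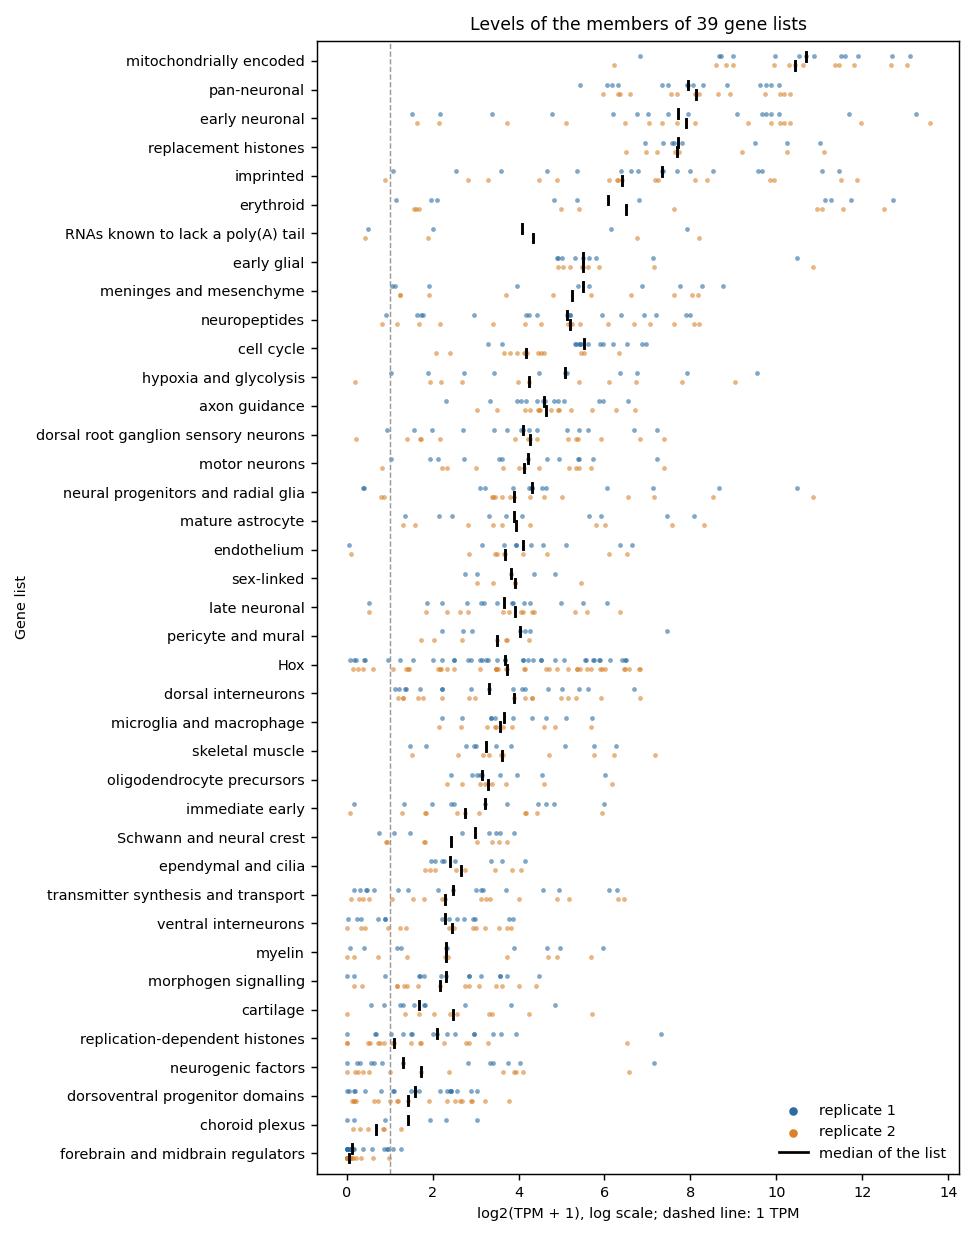
Level of each member of the 39 gene lists (rows) as log2(TPM + 1) on the horizontal axis, with blue points for replicate 1, orange points for replicate 2 and black bars for the median of the plotted values. The 18 forebrain and midbrain regulators lie at the left end, with 0 of them at or above 1 TPM in both libraries, and the 15 pan-neuronal genes lie near the right end.

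Cell state genes and other fixed groups completed the description. All 14 cell cycle genes were detected, led by Pcna at 102 ± 30.1 TPM, Cdk1 at 80.2 ± 50.2 TPM and Mcm6 at 67.0 ± 34.1 TPM, with the lowest at 5.99 ± 3.93 TPM (Mki67) and 7.8 ± 4.92 (Bub1). Of 11 immediate early genes, 10 were detected, and 6 at 5 TPM, led by Jun at 61.2 ± 1.11 TPM and Ier2 at 21.9 ± 7.45 TPM, while Fos stood at 4.79 ± 0.141 TPM and Fosb at 0.09 ± 0.0424. Of 11 hypoxia and glycolysis genes, 10 were detected, led by Ldha at 635 ± 160.1 TPM and Pgk1 at 231 ± 13.3 TPM, with Vegfa at 2.77 ± 0.106 TPM and Car9 at 0.6 ± 0.651 TPM lowest. The 13 mitochondrially encoded genes of the list took 3.17% of all TPM. Imprinted genes were detected in 16 of 17 cases, among them Nnat at 3296 ± 666 TPM, Meg3 at 2512 ± 532 TPM, Snrpn at 894 ± 121 TPM and Ndn at 839.8 ± 119 TPM, with Zim1 at 0.985 ± 0.191 TPM lowest. Igf2 exceeded Dlk1 by 1.84 ± 0.06-fold. All 5 sex-linked genes were detected in both libraries, with Xist at 19.6 and 14.1 TPM and Eif2s3y at 27.8 and 42.8 TPM in replicates 1 and 2. All 14 axon guidance genes were detected, led by Efnb3 at 97.9 ± 7.38 TPM, Robo2 at 68.97 ± 10.6 TPM and Nrp1 at 54.2 ± 4.45 TPM, with Robo3 of commissural axons lowest at 5.62 ± 2.3 TPM. Of 15 morphogen signalling genes, 12 were detected, and 6 at 5 TPM, led by Fgf9 at 20.7 ± 0.629 TPM, Wnt7b at 13.7 ± 1.85 TPM and Bmp7 at 11.1 ± 0.163 TPM. The floor plate signal Shh stood at 1.75 ± 0.686 TPM, and Wnt3a and Gdf7 were under 1 TPM (0.2 ± 0.113 and 0.06 ± 0.0849).

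Replacement histones, whose transcripts carry poly(A) tails, far exceeded replication-dependent histones, whose transcripts mostly do not. The difference was 6.42 ± 0.35 in mean log2(TPM + 1) (n = 2, exact permutation p = 1.85e-06, adjusted p = 1.3e-05), in 2 of 2 libraries. All 8 replacement genes were detected, led by H3f3a at 2141 ± 100.4 TPM and H3f3b at 1220.0 ± 0.834 TPM. Of 17 replication-dependent genes, 10 were detected, against 5 from CPM and 4 at 5 TPM, led by Hist1h4d at 124 ± 46.5 TPM and Hist1h1e at 11.6 ± 3.84 TPM, and Hist1h1a, Hist1h1d and Hist1h4a were under 1 TPM in both libraries (0.5 ± 0.113, 0.545 ± 0.106 and 0 ± 0). Of 4 other RNAs that lack a poly(A) tail, 3 were detected, Rn7sk at 267 ± 36.9 TPM, Rpph1 at 88.9 ± 25.8 and Rmrp at 2.87 ± 0.212, while Terc stood at 0.385 ± 0.0495. Histone copies share reads, so values of single histone genes were uncertain.

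Transcript isoforms were compared in 16 genes. The leading transcript was the same in both libraries in all but Pax6, Cdc42 and Gria2. Snap25-201 held 97.1 ± 0.19% of Snap25 TPM, Ncam1-204 held 68.8 ± 1.24% of Ncam1, Mapt-205 held 45.1 ± 0.15% of Mapt and Robo3-202 held 53.1 ± 0.02% of Robo3 (SD, n = 2). The kinase transcript Src-202 held 61.3 ± 5.12%, Dlg4-201 54.7 ± 2.36%, Dclk1-201 46.6 ± 1.23% and Nfasc-202 32.3 ± 2.24% of their genes. Xist-201 held 99.5 ± 0.70% of Xist, and App had 1 annotated transcript. Pkm, which encodes pyruvate kinase, differed most between the libraries in this set in percentage points. Pkm-202 stood at 60.6% in replicate 1, the library with more thymus and epithelium transcripts, and at 79.3% in replicate 2. In Pax6, Pax6-202 held 17.8% in replicate 1 and 30.02% in replicate 2, in Cdc42, Cdc42-201 held 46.6% and 54.6%, and in Gria2, Gria2-206, a retained-intron transcript, held 40.8% and 43.7%. Shares of expected counts, without division by length, gave 24.9% for Mapt-205 and 65.3% for Nfasc-202.

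Genes of thymus and epithelium were among the largest single-gene differences between the replicate pools. Over 17222 genes at or above 1 TPM in either library, Pearson's r of log2(TPM + 1) was 0.960 and Spearman's rho 0.959, a correlation across genes, which are not independent replicates. Of 11969 genes with enough signal, 400 were at least 2-fold higher in replicate 1 and 16 were at least 2-fold higher in replicate 2 on the TPM + 1 scale. Prss16 (ENSMUSG00000006179.4; chromosome 13, 22002173 to 22009742), a serine protease of the thymic cortex, stood at 136 and 0.07 TPM in replicates 1 and 2. Next by log2 ratio of TPM + 1 was the epithelial keratin Krt18 (254 and 1.57 TPM). Cd3g, part of the T cell receptor complex, followed at 93.0 TPM in replicate 1 and 0 counts in replicate 2, at least 392-fold lower when set against a floor of 3 counts in that library. Then came the keratin Krt8 (266 and 1.97 TPM) and the antigen presentation genes Cd74 (202 and 1.3 TPM) and H2-Ab1 (153 and 0.98 TPM). Gzma (75.6 and 0.1 TPM, with 2 counts in replicate 2), Tbata (57.97 and 0.03 TPM, with 1 count), Sprr2a2 (54.6 and 0.06 TPM, with 1 count) and Cldn7 (53.8 and 0.28 TPM) completed the 10 largest differences.

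Genes higher in replicate 2 differed by less. The prostaglandin synthase Ptgds stood at 33.1 and 95.8 TPM in replicates 1 and 2, a 2.89-fold difference, and the cartilage matrix gene Matn1 at 2.49 and 8.87 TPM. Hoxa5 (22.0 and 60.6 TPM) and Hoxb5 (32.4 and 86.7 TPM) followed, and then Eid2 (5.68 and 14.9 TPM), Gna12 (14.5 and 35.9 TPM), Dvl1 (9.45 and 23.4 TPM), the muscle creatine kinase Ckm (10.2 and 25.03 TPM), Selenon (6.9 and 15.9 TPM) and Gm14308 (11.2 and 24.7 TPM). The rule of size was no test, and the counts moved with the filter: 1099 and 181 genes without one, and 109 and 6 at a mean of at least 20 TPM. The labels give the libraries as separate pools of embryos, and their common biological coefficient of variation in edgeR was 0.362 across 20515 genes.

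**Figure D3:**
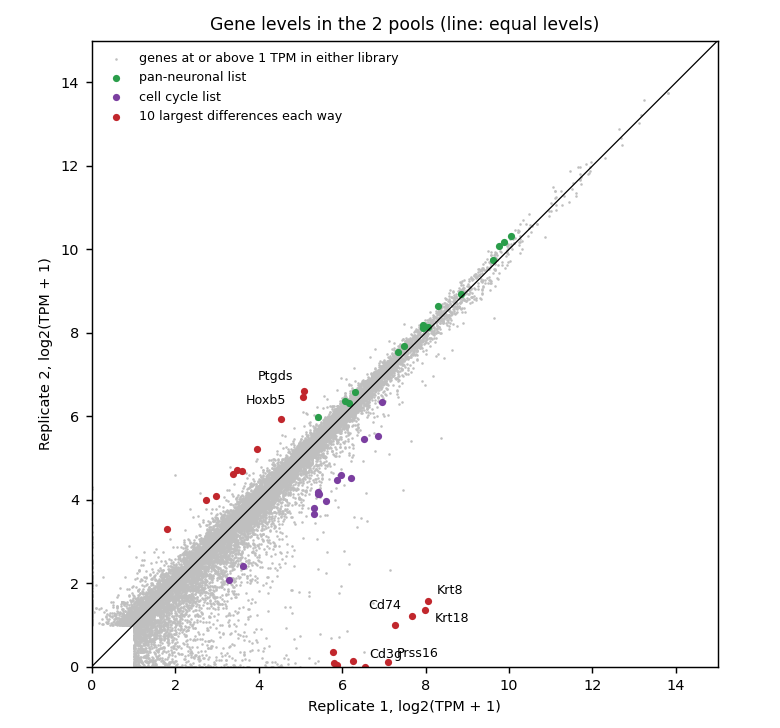
Level of each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis) as log2(TPM + 1), with the pan-neuronal list in green, the cell cycle list in purple and the 10 largest differences each way in red. Pan-neuronal genes lie slightly above the line of equal levels, and all 14 cell cycle genes lie below it.

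Whole gene groups shifted between the pools. Of 36 fixed lists with at least 4 expressed members, 23 had a median log2 ratio of replicate 2 to replicate 1 outside the central 95% of 10000 random lists matched on size and expression. Lists of independent genes would give 1.8. Members of a list may vary together, and some lists share members, so 1.8 is no chance rate for these lists and the count is a description. All 14 cell cycle genes were higher in replicate 1 (median -1.33), the library that also held more transcripts of thymus and epithelium, for example Ccnb2 (47.8 and 14.6 TPM) and Birc5 (72.6 and 21.9 TPM). Replication-dependent histones (median -0.75, 14 of 14 members), pericyte genes (median -0.53, 7 of 7), hypoxia and glycolysis genes (median -0.50, 9 of 11) and immediate early genes (median -0.33, 9 of 10) were also higher in replicate 1. Endothelial (median -0.30, 8 of 9), replacement histone (median -0.23, 5 of 8) and erythroid genes (median -0.20, 7 of 10) completed the 8 lists shifted that way.

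Neural, muscle and cartilage groups were higher in replicate 2. Skeletal muscle genes had a median log2 ratio of 0.63 (9 of 10 members), cartilage genes 0.59 (9 of 9), Hox genes 0.31 (25 of 35), progenitor domain genes 0.31 (10 of 13), ventral interneuron genes 0.28 (8 of 10) and sex-linked genes 0.30 (4 of 5, Xist being the member higher in replicate 1). Pan-neuronal and early neuronal genes had medians of 0.27 each (15 of 15 and 15 of 16), neuropeptides 0.22, transmitter genes 0.21, neurogenic factors 0.19, late neuronal genes 0.19, dorsal interneuron genes 0.18, dorsal root ganglion genes 0.17 and axon guidance genes 0.15. The progenitor list (median 0.03), oligodendrocyte precursors (median -0.03), myelin (median -0.05) and microglia (median -0.03) lay inside the range of random lists, as did 9 further lists. Within the Hox list, groups 1 to 4 and 5 to 9 had medians of 0.41 and 0.35, while groups 10 to 13 had a median of -0.50, with 7 of 9 expressed members higher in replicate 1. Intestine genes, a list added later, were also higher in replicate 1 (median -2.02, 5 of 6 members), with Cdx2 at 2.59 and 0 TPM in replicates 1 and 2. Scaling to the summed spike-ins moved the median of the 11969 compared genes from -0.01 to -0.12 and the progenitor list from 0.03 to -0.08. Under that scaling the shifts of the lists higher in replicate 2 shrank, to medians of 0.15 for pan-neuronal and early neuronal genes, 0.12 for dorsal interneurons, 0.11 for neurogenic factors, 0.10 for neuropeptides, 0.09 for transmitter genes, 0.08 for late neuronal, 0.06 for dorsal root ganglion and 0.04 for axon guidance genes. Hox (0.20), progenitor domain (0.21), ventral interneuron (0.18) and sex-linked genes (0.20), skeletal muscle (0.53) and cartilage (0.50) also fell, while erythroid (-0.32) and replacement histone genes (-0.35) moved further toward replicate 1. These ratios describe the 2 pools and test no condition.

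**Figure D4:**
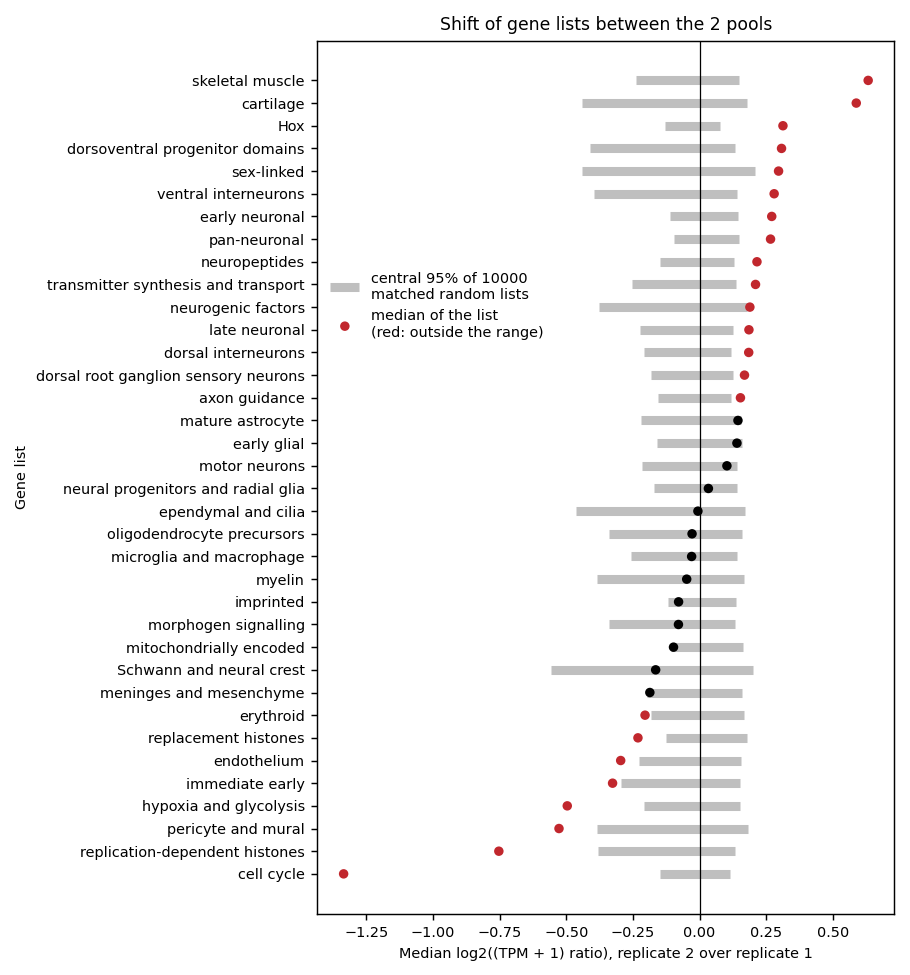
Median log2 ratio of replicate 2 to replicate 1 (horizontal axis) for the 36 fixed gene lists (rows), with grey bars for the central 95% of 10000 matched random lists and red points for medians outside it. The cell cycle list stands apart at -1.33, and skeletal muscle (0.63) and cartilage (0.59) lie at the other end.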

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

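Expected counts were present on number-only entries, a part of the tables outside the gene analyses: 23 in replicate 1, on 7 of 26248 entries, and 27 in replicate 2, on 8. A count of 0 would have allowed up to 3, and the phage control had 0 in both libraries.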

How the results depend on the processing

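Most results kept their direction and their side of the threshold. A count was called the same within a ratio of 1.5, a list difference on the same side of an adjusted p of 0.05 with the same sign, and r inside its 95% interval. A pair ratio, isoform share or Hox share was called the same within the SD of the 2 libraries, and a list shift within the SD of random lists. With 1 of 2 replicates left out, a pair ratio or isoform share always lies within that SD, so its label there was fixed in advance and tests nothing. Of the values that answer a question of the report, recomputed under an alternative, 71 were the same by these rules, 7 moved, 2 passed the threshold that they had missed, 1 no longer passed it, and 0 changed sign. The rule for counts is wide. The count of genes detected in both libraries ranged from 11469 at 5 TPM to 18823 with posterior means, against 15505, and was 16001 without replicate 1 and 16726 without replicate 2. The difference between early glial and mature astrocyte genes passed the threshold on TMM-normalized CPM (2.26, adjusted permutation p = 0.024) and with medians over genes (1.68, adjusted permutation p = 0.022), over a range of adjusted p from 0.022 to 0.12. Progenitor minus neurogenic genes no longer passed with members under 1 TPM left out (1.91, adjusted permutation p = 0.076, range 0.0044 to 0.076), where fewer genes were compared. Genes higher in replicate 1 numbered 1099 and in replicate 2 181 without a filter, and 109 and 6 at a mean of at least 20 TPM, since the filter sets how many genes are compared. Across the replicates, r was 0.913 with a pseudocount of 0.1, 0.979 over genes at or above 1 TPM in both and 0.985 over all genes. Among single lists, pairs, isoforms and Hox groups, 389 values were the same by these rules and 74 moved, with 0 changes of sign among called values. The 389 include 15 pair ratios and 16 isoform shares for each replicate left out, whose label could not have differed. Length-free CPM moved 12 of 15 pair ratios, and spike-in scaling moved 21 of 46 list shifts. The count of fixed lists outside the random range does not test the scaling, because random lists shift with it. No paired analysis was possible because there is only 1 group. Depth limits genes with few counts: Hoxa13, for example, rested on 3 counts in replicate 1 and 9 in replicate 2.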

Other observations

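The following lists and named genes were added after the largest differences between the libraries had been seen. Smooth muscle and gut transcripts were higher in replicate 1. The 6 smooth muscle genes had a median log2 ratio of replicate 2 to replicate 1 of -2.88 (6 of 6 higher in replicate 1), with Actg2, the enteric actin, at 105 and 1.89 TPM in replicates 1 and 2, Myh11 at 14.9 and 0.31 TPM and Tagln at 27.04 and 5.31 TPM. The 6 intestine genes had a median of -2.02 (5 of 6), with Vil1 at 4.83 and 0.27 TPM, Fabp1 at 4.86 and 0.17 TPM and Cdx2 at 2.59 and 0 TPM. The 6 liver genes had a median of -1.37 (6 of 6), with Afp at 9.6 and 2.51 TPM and Alb at 3.96 and 1.71 TPM. Bladder (-0.74), heart (-0.15) and skin genes (-0.03) lay inside the range of random lists. The lung, stomach, kidney and airway lists had fewer than 4 members at 1 TPM, with list sums of 1.16 ± 0.41, 0.77 ± 0.86, 3.79 ± 1.87 and 48.9 ± 68.8 TPM (n = 2), the last mostly from Sprr2a2 (54.6 and 0.06 TPM) and Bpifa1 (42.1 and 0.09 TPM).

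Muscle and cartilage genes beyond the fixed lists were higher in replicate 2. The 9 expressed members of a wider muscle list had a median of 0.49 (9 of 9 higher in replicate 2), and the 10 members of a wider cartilage list had a median of 0.34 (7 of 10). T cell receptor and thymus genes outside any list followed Cd3g: Trbc1 stood at 74.5 and 0 TPM in replicates 1 and 2, Trbc2 at 139.7 and 4.01 TPM, Tcrg-C1 at 91.2 and 0.27 TPM, Cd3e at 39.9 and 0.06 TPM, Cd3d at 28.4 and 0.06 TPM, Ptcra at 35.8 and 0.16 TPM and Psmb11 at 22.3 and 0.03 TPM.

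Of the tests below, those of thymus tissue, of lymphocytes and of GC content and length were written before their values were seen, though after the largest differences were known, and the tests of a mislabelled tissue, of neural progenitors, of dividing cells, of the head-to-tail span and of the neural share were chosen after the results were seen. For the Hox pattern, hindgut tissue in replicate 1 was weighed earlier, through Hoxa13 (0.06 and 0.2 TPM in replicates 1 and 2) and Hoxd13 (0.17 and 0.11 TPM). It was replaced by the neural share after those values were seen, because both genes lay near the floor, so it was not excluded, and the intestine genes above were higher in the same library as the posterior Hox genes. The design holds 1 group, so it names no biological difference to set against these explanations. The bootstrap ranges below resample genes within these 2 libraries and do not measure the spread between pools.

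Genes of thymus and epithelium were far higher in replicate 1. Lymphocytes without thymic epithelium are argued against by the thymic epithelium list, which had a median log2 ratio of -3.06 (95% bootstrap range -3.63 to -1.50, 10 of 10 members, 4 of them detected in both libraries), with Ccl25 at 86.9 and 10.7 TPM, Epcam at 60.03 and 2.37 TPM and Foxn1 at 9.69 and 0 TPM in replicates 1 and 2. A library of another tissue under the neural tube label is argued against by the pan-neuronal list, whose median was 0.27 (0.15 to 0.31). Thymus tissue carried into the pool of replicate 1 remains a candidate explanation: the thymocyte list, 3 of 16 members of which were detected in both libraries, had a median of -2.14 (-3.35 to -1.52, 11 of 11 expressed members), with Lck at 81.5 and 9.17 TPM and Rag1 at 9.52 and 0.03 TPM. A member that reached 1 TPM in replicate 1 alone was bound to be higher there, so the filter partly set that count and median. Over all 16 members, without the filter, the median was 3.045 TPM in replicate 1 and 0.085 TPM in replicate 2, and 5 members were under 1 TPM in both. The gut, smooth muscle and liver genes above are not thymic, so other tissues may have come along.

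Cell cycle genes were higher in replicate 1 in 14 of 14 cases. More neural progenitors, as a share of the whole library, are argued against by the progenitor list, whose median log2 ratio was 0.033 (95% bootstrap range -0.15 to 0.27). Its expressed members ran from -0.89 (Notch1) to 0.49 (Hes5). The pan-neuronal median was 0.27, so a rise of progenitors relative to neurons in replicate 1 is not excluded. Dividing cells of the carried-over tissue could account for the cell cycle list's median of -1.33 (-1.54 to -1.21), but the extra tissue and the higher cell cycle genes occur in the same library, so that source cannot be told apart from faster division in the neural tube itself.

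Posterior Hox genes were higher in replicate 1, and central Hox genes in replicate 2. A bias of GC content or length is argued against, since removing its trend over 11910 genes kept 1.02 of the gap between paralogues 4 to 9 and 10 to 13 (0.85 before, 0.87 after). A different head-to-tail span of tissue in the 2 pools cannot be told apart, because the fall of the log2 ratio with the paralogue number in 4 of 4 clusters (Spearman's rho of -0.52, -0.32, -0.47 and -0.93 for Hoxa, Hoxb, Hoxc and Hoxd, across genes) restates the pattern. A lower share of neural tissue in replicate 1 may account for the median of the central genes. That median, 0.35 (95% bootstrap range 0.17 to 0.61), lay near the 0.27 of pan-neuronal genes. Single central genes ran from -0.09 (Hoxd9) to 1.39 (Hoxb5) and 1.42 (Hoxa5), so a common share does not account for each of them. For the posterior genes, with a median of -0.50 (-0.98 to 0.60), a lower neural share cannot be told apart, because 9 expressed genes are too few and Hoxb13 and Hoxc13 went the other way.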
